A study of Mus musculus with 2 samples.

How the data were processed

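ChIP-seq for H3K4me1 had been done on the livers of mouse embryos at 12.5 days, in 2 samples of 1 group. Per the labels, the samples were separate pools of 120 and 88 embryos of both sexes, numbered as biological replicates 1 and 2. Per the labels, the coordinates are on mm10, which is GRCm38. The aligner, peak caller, thresholds and filters are not given in the sources used here, nor is the read depth, so the precision that depth gives cannot be stated and a region without a peak may have had too few reads.

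The deposited files were 4 peak lists in narrowPeak format without a header. Per the deposited lists of files, 1 list was called by the authors on the alignments of each replicate with control reads, 1 on the alignments of both replicates together with control reads, and 1 replicated list was derived from both replicates' lists and the pooled list. The rule for keeping a peak as replicated is not given in the sources used here. Every peak of the replicated list is also a peak of the pooled list. The deposited fold of each peak is the authors' ratio of ChIP over control, and the deposited −log10 q of each peak is the authors' significance. Both are values of the peak in its own list, and were used to describe, rank or filter peaks within a list. They were also correlated by rank between the replicates' lists, and the fold in the replicated list was compared between gene lists. The score, −log10 p and summit columns, 3 in each list, were not used.

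Positions were compared with the GENCODE M21 annotation of GRCm38, after the chromosome names and lengths had been checked against the GRCm38 sequence. The TSS was the 5′ end of each of 21938 protein-coding gene records on chromosomes 1 to 19, X and Y. A peak was assigned by its midpoint to a promoter (within 1 kb of a TSS), else an exon, else an intron, else to intergenic sequence. Peaks on other scaffolds were left out of these comparisons. Shuffled lists held the same peaks placed at random without overlap in the sequenced bases of the same chromosome, 100 times with a fixed seed. The percent of TSSs covered was taken in steps of 100 bp to 5 kb on each side.

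For the gene lists, a locus was the gene with 20 kb on each side, and its value was the percent of bases covered by peaks. The list's median was placed among 10000 random lists of the same size, each member drawn from genes in the same decile of locus length and the same quintile of the number of TSSs within 500 kb. The list was called high in the highest 2.5% of random lists and low in the lowest 2.5%. This is a description, since genes are not replicates, and no p-value was computed. The 20 gene lists, their comparison with random lists and most of the alternatives were fixed before the data were examined. Tests chosen after values had been seen are said to be so. Ahsp in the erythroid list and C5 in the coagulation list were not found in the annotation under these symbols. The genes named are the 3 members with the highest value and the 1 with the lowest of each list, every embryonic globin, the genes at the 20 longest domains and the 10 peaks with the highest fold, and the 10 genes with the highest coverage among loci of at least 50 kb. Domains were replicated peaks joined where at most 1 kb apart. Genes chosen after their values were seen are said to be so.

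Alternatives were other overlap rules, a −log10 q of at least 5, other flanks, each replicate's own list, the pooled list, other matching and other joining distances. Alternatives added after the data were seen were matching on GC content, counting overlapping loci once, leaving out peaks within 1 kb of a TSS, and windows of 20 kb around the TSS. The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data. With 300 random lists of 20 from the 21938 genes and nothing added, 4.67% of lists were called high and 3.00% low. With 5, 10 and 20 percentage points of coverage added to each member, 18.7%, 72.0% and 100% were called high. The number of replicate 1 peaks overlapping replicate 2, 124843, was the same with bedtools 2.31.1.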

Results

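H3K4me1, the monomethylation of histone H3 at lysine 4 that marks enhancers and the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the livers of B6NCrl mouse embryos at 12.5 days of development. At this stage the liver is the main site of red blood cell formation and also holds hepatoblasts, the precursors of hepatocytes and bile duct cells. The 2 samples were separate pools of embryos of both sexes and formed 1 group. Replicate 1 was a pool of 120 embryos with 2 technical replicates, and replicate 2 was a pool of 88 embryos with 1 technical replicate. The labels gave a size range of 300 to 500 bp for the libraries. There was no second tissue, age or treatment, so the design asks where H3K4me1 peaks lay and how far the 2 pools overlapped. The depth of the libraries is unknown, since the deposited values are peak lists. Beside the main values stand the separate values of the 2 replicates' own lists, which show the spread between the pools. The main values come from the replicated list, a subset of the peaks called on both replicates' reads together. They are not means of the replicates and often lie above both, so the replicates' values are not their error. Values printed alone carry no error, and no p-value was computed.

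Replicate 1 had 164331 peaks covering 94.7 Mb, and replicate 2 had 181403 peaks covering 112 Mb. The list called on the reads of both replicates together had 206516 peaks covering 144 Mb. The authors' replicated list, which is a subset of that pooled list, had 112926 peaks covering 119 Mb, or 4.49% of the sequenced bases of chromosomes 1 to 19, X and Y. The median width of a replicated peak was 698 bp, with quartiles of 435 and 1238 bp, against 338 bp in replicate 1 and 348 bp in replicate 2. The median of the authors' fold enrichment per peak was 3.37 in the replicated list, 3.04 in replicate 1 and 3.21 in replicate 2. A −log10 q of at least 5 was reached by 80.7% of the replicated peaks, 38.4% of replicate 1's peaks and 39.2% of replicate 2's peaks. The replicated peaks carry the values of the call on both replicates' reads together, so these values are not on 1 scale with those of the replicates. In the whole pooled list the median width was 378 bp, the median fold was 2.68, and 48.3% of peaks reached that −log10 q. No list had a peak on chromosome Y or on the mitochondrial genome.

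The authors kept 54.7% of the pooled peaks in the replicated list. The share kept was 8.997% in the lowest decile of the pooled peaks by fold and 100% in the highest decile. Of the kept peaks, 93984 (83.2%) overlapped a peak in both replicates' own lists and 0.764% overlapped neither. The 93590 pooled peaks that were not kept had a median width of 234 bp, and 0.987% of them overlapped both replicates' lists.

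Peaks of the 2 pools of embryos overlapped far more often than shuffled peaks. Of replicate 1's peaks, 76.0% overlapped a peak of replicate 2 by at least 1 bp, against 9.11% ± 0.0735 (SD over 100 shuffles within chromosomes). Of replicate 2's peaks, 62.6% overlapped a peak of replicate 1, against 6.89% ± 0.0538 in the shuffles. With a reciprocal overlap of at least 50%, these shares were 41.3% and 37.5%. The replicates shared 74.2 Mb, which was 78.4% of the bases covered in replicate 1 and 66.0% of those covered in replicate 2, and 55.9% of the bases covered in either (2.30% ± 0.0269 in the shuffles). Strong peaks were shared most: 99.97% of replicate 1's peaks in the highest decile of fold overlapped replicate 2, and 99.84% of replicate 2's peaks in that decile overlapped replicate 1. In the lowest decile these shares were 61.2% and 41.4%. Across 141052 overlapping pairs of peaks, Spearman's rho between the replicates was 0.45 for the authors' fold and 0.53 for −log10 q. Peaks are not independent replicates. Across 21938 protein-coding loci, where a locus is the gene with 20 kb on each side, the percent of the locus covered had a Spearman's rho of 0.99 between the replicates, again across genes, which are not independent.

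Erythroid loci were densely covered by H3K4me1 peaks. The 35 erythroid genes in the annotation had a median of 36.7% of the locus covered in the replicated list (28.4% in replicate 1 and 34.7% in replicate 2), while the median of random lists matched on locus length and gene density was 9.66%, with all but the lowest and highest 2.5% of them between 4.68% and 15.6%. The list's median lay at the 100th percentile of 10000 such lists. Of the 35 genes, 25 lay above the 75th percentile of their matched genes, 1 lay below the 25th, and 34 had a peak within 2 kb of the transcription start site (TSS). The highest were Zfpm1, which encodes the GATA1 cofactor FOG1, at 78.1% (74.0% in replicate 1 and 76.0% in replicate 2), Bcl2l1, which encodes the survival factor BCL-XL, at 65.7% (60.3% and 61.4%), and the adult alpha-globin gene Hba-a1 at 61.6% (51.4% and 57.2%). The lowest was the alpha-spectrin gene Spta1 at 5.60% (4.62% and 4.85%). Gata1 and Klf1, erythroid transcription factors named after their values were seen, were covered over 20.4% and 39.8% of the locus. Gata1, which lies on X, was near the middle of its matched genes, at their 52.98th percentile, and Klf1 was at the 84.82nd. Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical copies whose reads can be assigned to either, so their separate values are uncertain.

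The loci of all 3 embryonic globin genes, which serve the first red cells of the embryo, had high coverage. Hba-x was covered over 66.9% of its locus (54.7% in replicate 1 and 65.8% in replicate 2), Hbb-y over 57.4% (43.5% and 54.8%) and Hbb-bh1 over 50.6% (38.2% and 48.9%). The list's median lay at the 99.96th percentile of random lists. The Hbb-y and Hbb-bh1 loci overlap each other, so the list held 2 separate loci. The locus of Hba-x also contains the adult genes Hba-a1 and Hba-a2, and that of Hbb-bh1 contains Hbb-bs, so the list is not independent of the erythroid list. The list's percentile was 89.5 with 100 kb of flank and 97.45 with 5 kb, which misses the highest 2.5% that was called high. The 8 genes of heme synthesis had a median of 30.7% (26.2% and 28.5%), at the 99.78th percentile, with 7 of 8 above the 75th percentile of their matched genes. Ppox, Alad and Fech, enzymes of the heme pathway, were the highest at 49.8%, 39.8% and 36.2%, and Urod was the lowest at 15.8%. With 100 kb of flank the heme list was at the 90.98th percentile. Alas2 was a member of both the erythroid and the heme list.

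Genes of hematopoietic stem and progenitor cells were also high. The median of the 22 genes was 27.9% (21.4% in replicate 1 and 24.999% in replicate 2) against 4.71% in random lists, at the 100th percentile, and 18 of the 22 lay above the 75th percentile of their matched genes. Lyl1, a basic helix-loop-helix transcription factor of blood progenitors, was covered over 62.1% (54.7% and 58.2%), Gfi1b, a transcriptional repressor of the erythroid and megakaryocytic lineages, over 59.8% (55.9% and 58.1%), and Cbfa2t3, which encodes a corepressor of that lineage, over 54.1% (48.4% and 50.2%). Mecom, a regulator of stem cells, was the lowest at 0.540% (0.276% and 0.655%). The 17 megakaryocyte genes had a median of 16.9% (14.01% and 16.0%) at the 97.23rd percentile, just outside the highest 2.5%, and 10 of the 17 lay above the 75th percentile of their matched genes. Their highest members were the platelet glycoprotein genes Gp9 at 53.9% and Gp1ba at 48.2% and the granule gene Nbeal2 at 41.0%, and Gp6 was at 0%. With each replicate's own list the megakaryocyte list passed the threshold, at percentiles of 97.94 in replicate 1 and 97.58 in replicate 2. It stayed below the threshold in other settings, such as 94.59 with 100 kb of flank and 94.13 with matching on GC content.

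The list of mature hepatocyte metabolism genes had low coverage. The median of the 26 genes was 0% in the replicated list, 0.180% in replicate 1 and 0.0901% in replicate 2, against 6.97% in random lists, at the 0.035th percentile. Of the 26 loci, 15 had no replicated peak, the other 11 had from 1 to 14, and 16 lay below the 25th percentile of their matched genes. The urea cycle genes Cps1 and Otc, the tyrosine catabolism gene Tat and the cytochrome P450 genes Cyp2e1 and Cyp3a11 were among those at 0%, also in both replicates' own lists. Otc lies on X, where the median of all loci was 0%, and the random lists were not matched on chromosome. The highest members of the list were Hpd, an enzyme of tyrosine catabolism, at 26.2% (23.0% and 22.8%), the bile acid transporter gene Slc10a1 at 18.3% (16.7% and 17.1%) and the glutamine synthetase gene Glul at 13.6% (7.66% and 13.2%). The list holds members of cytochrome P450 and major urinary protein gene families, whose copies resemble each other. Of the 26 genes, 13 had no like-named neighbour within 500 kb, and this group was chosen after the values were seen. Like-named symbols are the same once the number at the end, with any letter in it, is removed, so Slc10a1 counted as having a neighbour. The 13 members without one had a median of 1.87%, at the 8.80th percentile of random lists, and were not called low. Those lists were drawn from all genes, with and without neighbours. This percentile thus cannot tell whether these members are low among genes without neighbours.

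The 34 hepatoblast and fetal hepatocyte genes lay within the range of random lists, with a median of 6.48% (5.33% in replicate 1 and 6.94% in replicate 2) against 5.95%, at the 57.18th percentile. Against lists also matched on GC content, a setting added after the data were seen, the list was at the 6.96th percentile. The median of those lists was 10.2%, so the list's place within the range depended on the matching. The values of the 34 genes were spread widely: 5 lay above the 75th percentile of their matched genes, 6 below the 25th, and 5 had no replicated peak. The hepatic lipase gene Lipc was covered over 38.4% (30.9% and 36.7%), the apolipoprotein gene Apoa2 over 32.9% (23.4% and 28.5%) and Foxa3, which encodes a liver transcription factor, over 30.5% (24.9% and 30.6%). The albumin gene Alb was covered over 1.03% (0.478% and 1.37%), and the alpha-fetoprotein gene Afp and the transthyretin gene Ttr had no replicated peak. The 21 coagulation and complement genes had a median of 4.24% (1.77% and 3.98%), at the 20.35th percentile, and 10 of them lay below the 25th percentile of their matched genes. Their highest members were F2, the prothrombin gene, at 23.9%, Cfb at 21.0% and Cfi at 18.6%, and F9, which lies on X, was among 5 at 0%. The 12 cholangiocyte genes had a median of 2.95% (2.19% and 2.14%), at the 38.74th percentile, with Notch2 at 32.8%, Hes1 at 25.1%, Sox4 at 16.9% and Pkhd1 at 0%. Where members of a list tied at 0, those named were chosen after the values were seen, as were Alb, Afp and Ttr.

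Macrophage genes were low. The median of the 17 genes was 0% (0.432% in replicate 1 and 0.232% in replicate 2) against 7.47% in random lists, at the 0.22nd percentile, and 9 of the loci had no replicated peak, among them the complement gene C1qa. The lysosomal gene Cd68 was the exception at 48.4% (37.7% and 49.2%), followed by the immunoglobulin receptor gene Fcgr1 at 16.6% and the chemokine receptor gene Cx3cr1 at 13.998%. With 100 kb of flank the macrophage list lay at the 17.72nd percentile, so its low value held with 5 and 20 kb of flank only. The other cell types lay within the range. The 16 endothelial genes had a median of 11.9% (8.58% and 10.9%), at the 78.13th percentile, with Eng at 39.8%, Lyve1 at 36.1%, Stab1 at 27.5% and Emcn at 0%. The 13 granulocyte and mast cell genes had a median of 6.94% (5.59% and 8.70%), at the 42.12th percentile, with Prtn3 at 30.4%, Elane at 26.5%, Cebpe at 16.4% and Mcpt8 at 0%. The 16 lymphoid genes had a median of 5.38% (3.70% and 4.74%), at the 27.17th percentile, with Lck at 27.3%, Cd79a at 25.9%, Cd19 at 13.1% and Cd8a at 0%. The 19 stellate, mesenchymal and mesothelial genes had a median of 2.39% (1.93% and 2.26%), at the 14.41st percentile, with Pdgfrb at 20.4%, Des at 9.03%, Lhx2 at 7.76% and Dcn at 0%.

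The lists of other tissues lay within the range and the housekeeping list above it. The 19 neuronal genes had a median of 2.58% (2.12% in replicate 1 and 1.85% in replicate 2), at the 22.63rd percentile, with the tubulin gene Tubb3 at 23.7%, Slc17a7 at 18.6%, Grin1 at 16.1% and Neurod6 at 0%. The 18 genes of cardiac and skeletal muscle had a median of 4.21% (3.54% and 4.40%), at the 35.08th percentile, with Tnni3 at 36.2%, Myl7 at 26.96%, Tnnt2 at 16.9% and Actc1 at 0%. The 14 genes of pancreas and intestine had a median of 3.58% (2.35% and 3.17%), at the 28.11th percentile, with Vil1 at 25.9%, Cdx1 at 19.6%, Cpa1 at 11.1% and Ins1 at 0%. The 39 Hox genes had a median of 5.79% (4.15% and 6.21%), at the 41.85th percentile. They lie in clusters that made 8 separate loci, Hoxa5, Hoxa6 and Hoxa4 had the highest values at 14.4%, 11.9% and 11.1%, and Hoxc12 was at 0%. The 16 housekeeping genes had a median of 28.8% (24.5% and 25.7%), at the 99.99th percentile, with the elongation factor gene Eef2 at 57.0%, Rpl13a at 51.6% and Tubb5 at 51.2%. Pgk1, which lies on X, was the lowest of them at 5.02%. Of the 1135 olfactory receptor genes, 1045 had no replicated peak, and the list lay at the 0th percentile. Against random lists that were also matched on GC content, the muscle, Hox and stellate lists were low as well, at percentiles of 0.14, 0 and 0.47. The Hox value takes the 39 genes as separate though they made 8 loci, so its random range may be too narrow. With overlapping loci counted once, without matching on GC content, the Hox list was at the 21.84th percentile, and these settings were not combined. With matching on GC content, the hepatoblast, coagulation and neuronal lists moved down but stayed within the range, at percentiles of 6.96, 5.16 and 4.79. For the olfactory receptors the random lists matched on GC content also had a median of 0%, so this comparison could not place them. Among lists drawn at random, a few percent are expected outside the range.

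**Figure D1:**
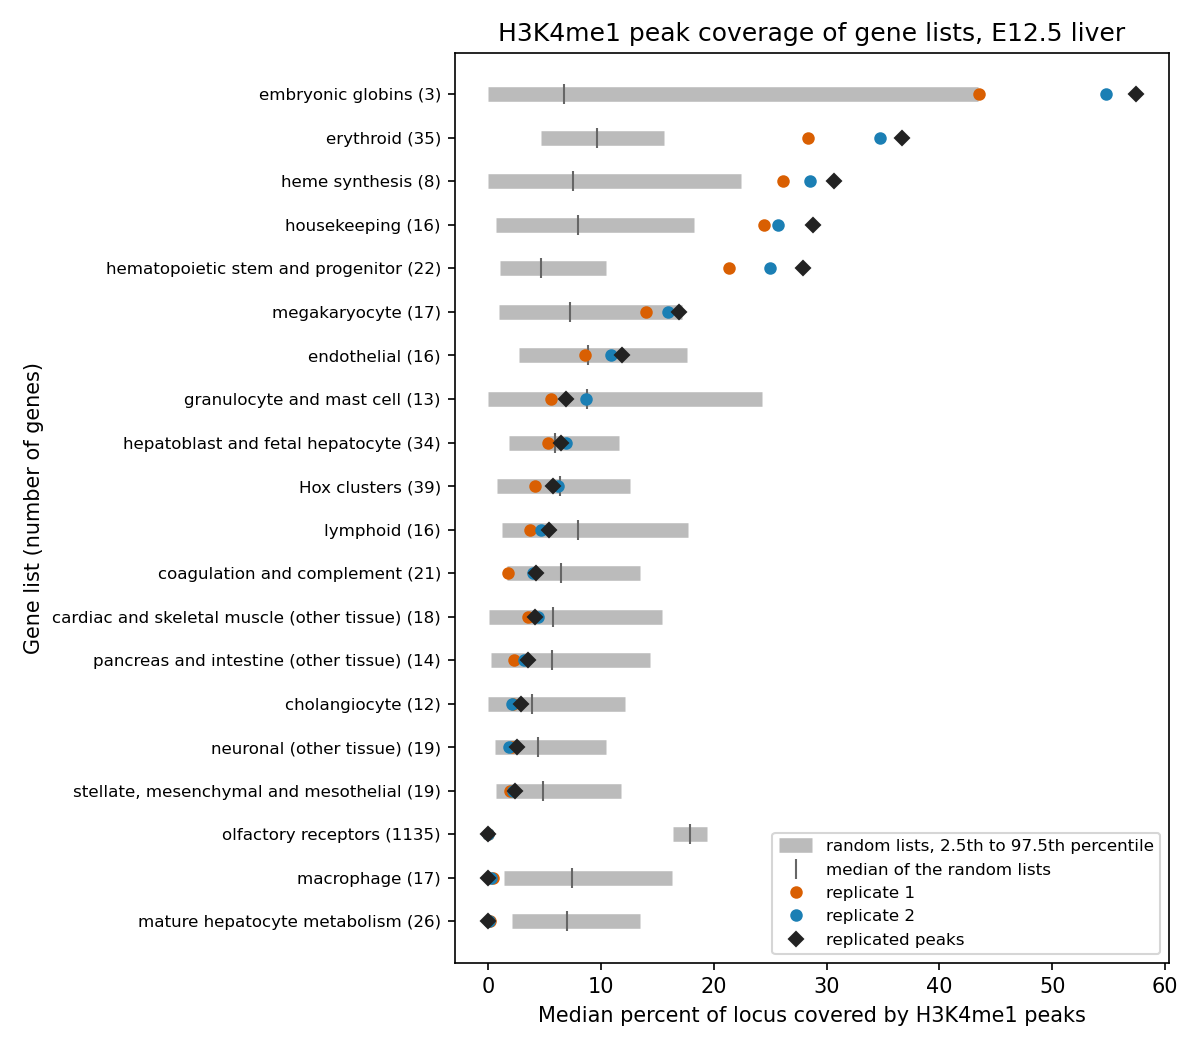
Median percent of locus covered by H3K4me1 peaks (x axis) for each gene list (y axis, number of genes in parentheses), with the replicated peaks as diamonds, each replicate's own list as dots, and 10000 matched random lists without their lowest and highest 2.5%, scored on the replicated peaks, as grey bars. The erythroid list stands at 36.7% and the mature hepatocyte list at 0%.

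The following 3 regions were chosen after the values were seen, to show loci with high and low coverage, and do not stand for their lists: Zfpm1 is the highest erythroid locus, and other hepatoblast loci such as Lipc and Apoa2 were well covered. On chromosome 8, the region from 122262141 to 122357251 (mm10), which holds Zfpm1, had 13 replicated peaks over 78.1% of its bases. On chromosome 11, the region from 32256400 to 32317298, which holds the alpha-globin genes Hba-x, Hba-a1 and Hba-a2 and part of their neighbour Nprl3, had 21 replicated peaks over 52.1% of its bases (43.4% in replicate 1 and 50.6% in replicate 2). On chromosome 5, the region from 90440897 to 90528907, which holds Alb and Afp, had 2 replicated peaks over 0.652% of its bases (0.302% and 0.869%), both upstream of Alb.

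**Figure D2:**
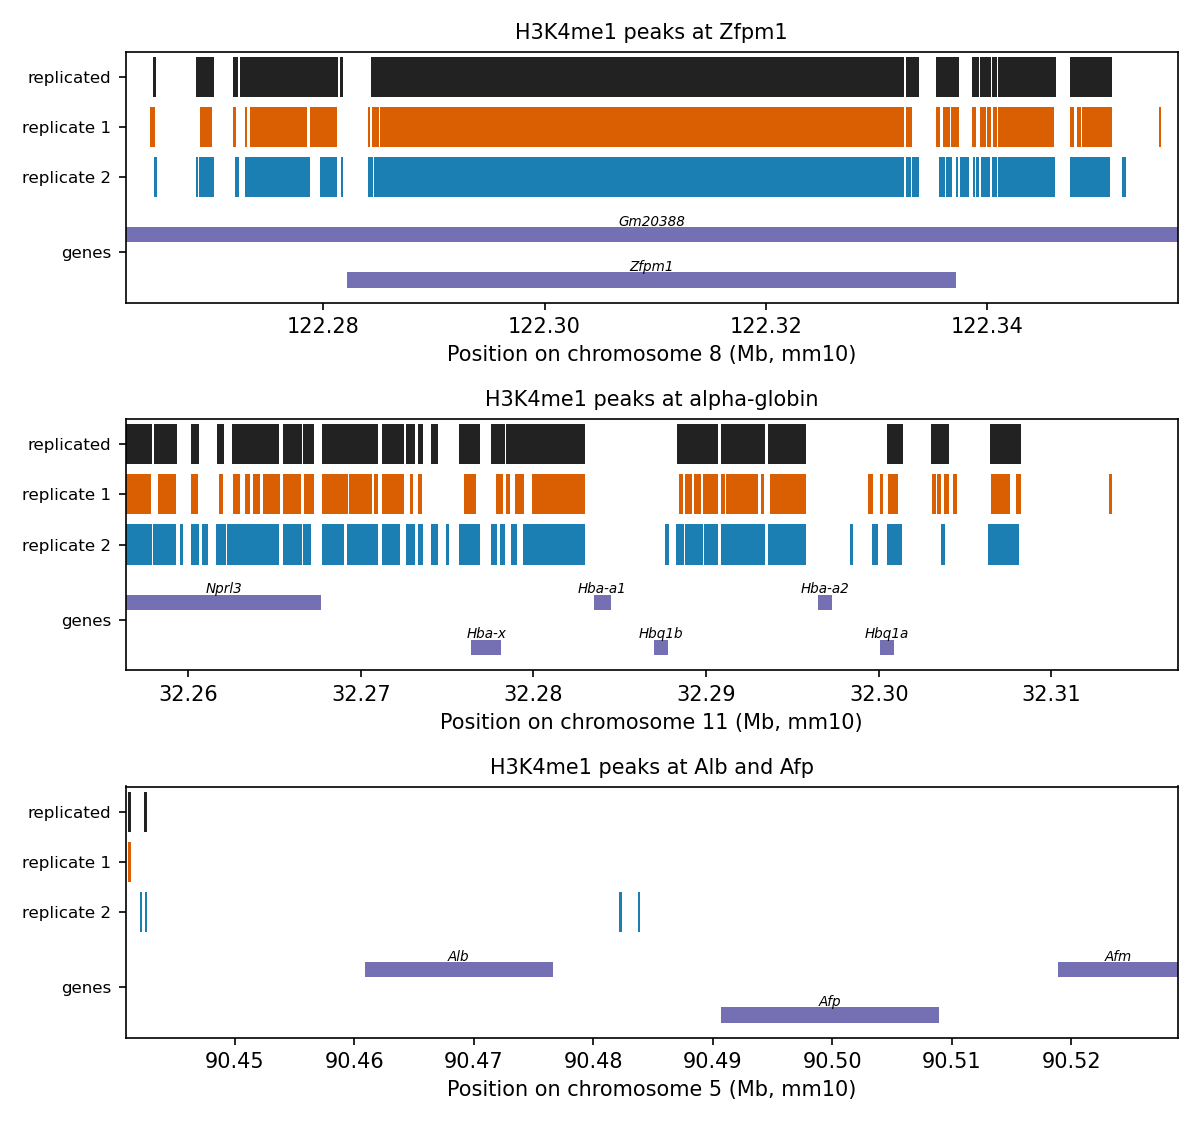
Maps of the Zfpm1, alpha-globin and Alb and Afp regions, with position in Mb on the x axis and rows for the replicated peaks, each replicate's own peaks and the protein-coding genes. Boxes are peaks or genes drawn to scale, and peaks cover 78.1%, 52.1% and 0.652% of the 3 regions in the replicated list.

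Most peaks lay in introns or between genes. Of the replicated peaks, 55.8% had their midpoint in a protein-coding intron (56.7% in replicate 1 and 56.4% in replicate 2), against 37.3% ± 0.129 (SD) in 100 shuffles. A further 26.9% were intergenic (26.7% and 27.8%), against 57.4% ± 0.117 in the shuffles, and 6.95% were in exons (7.14% and 6.92%), against 3.57% ± 0.0551. Promoters, within 1 kb of a protein-coding TSS, held 10.4% of the peaks (9.46% and 8.89%), which was 6.13 times the shuffled share of 1.70% ± 0.0362. With promoters taken as within 2 kb, they held 18.5% of the peaks. The median distance from a peak's midpoint to the nearest protein-coding TSS was 14687 bp, against 68723 bp in the shuffles, and 57.8% of the peaks lay farther than 10 kb from one. The median fold was 3.81 for promoter peaks and 3.27 for intergenic peaks.

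**Figure D3:**
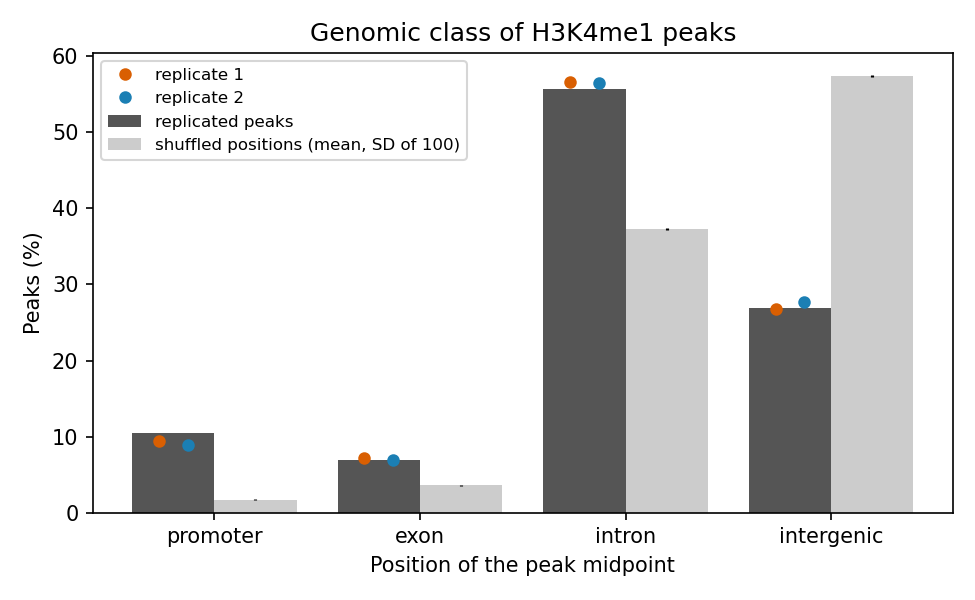
Percent of H3K4me1 peaks (y axis) by the position of the midpoint (x axis), with dark bars for the replicated list, dots for the replicates, and pale bars for the mean of 100 shuffles with their SD. Promoters held 10.4% of the peaks and 1.70% of shuffled peaks.

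Around the TSS the peaks formed shoulders with a dip between them. At the TSS itself 20.1% of 21938 protein-coding genes were covered by a replicated peak (14.8% in replicate 1 and 17.0% in replicate 2), the lowest value between the shoulders. At 600 bp upstream 34.2% were covered (27.1% and 31.2%), the upstream maximum. The downstream maximum was 39.0% at 1000 bp in the replicated list, and 32.3% and 36.7% at 1100 bp in the replicates. At 5 kb upstream the share was 10.2% and at 5 kb downstream 14.8%. A peak lay within 5 kb of the TSS of 14495 genes (66.1%), and 5266 genes (24.0%) had no covered base in the gene or in the 20 kb on each side.

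**Figure D4:**
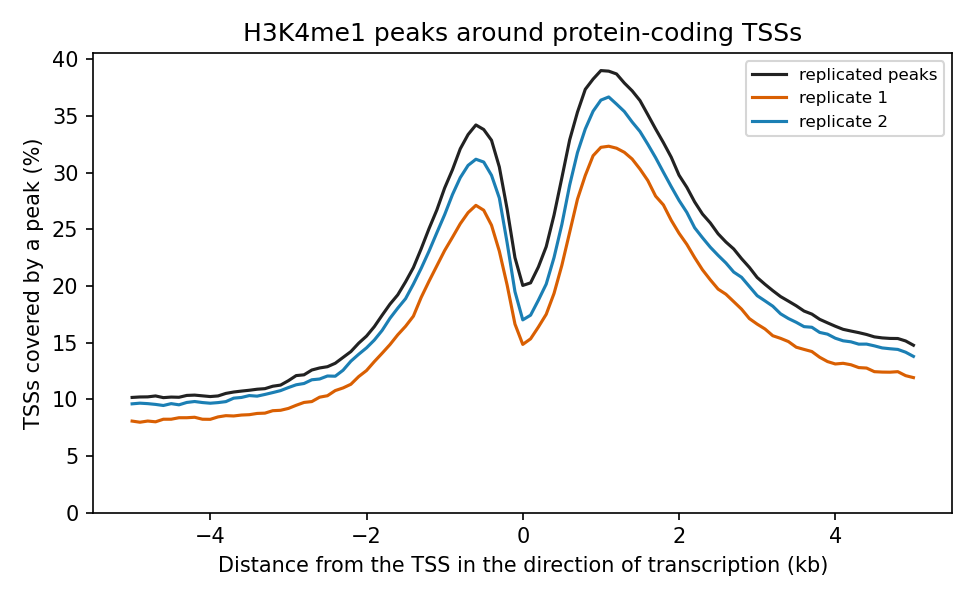
Percent of protein-coding TSSs covered by an H3K4me1 peak (y axis) at each distance from the TSS in kb (x axis), with a line for the replicated list and for each replicate. All 3 lines dip at the TSS, where the replicated list covers 20.1%, and reach their maximum downstream, at 39.0% in the replicated list.

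The broadest domains, made by joining replicated peaks at most 1 kb apart, lay mainly in introns. The longest was 76.3 kb long, on chromosome 8 from 120489810 to 120566083 in Gse1, and was covered over 90.2% in replicate 1 and 94.7% in replicate 2. The next were 60.9 kb in Foxo3, which encodes a forkhead transcription factor (chromosome 10, 42213959 to 42274847), 60.8 kb in March3, which encodes a ubiquitin ligase, 59.5 kb in Bcl11a, which encodes a repressor of globin genes (chromosome 11, 24091439 to 24150939), and 57.9 kb in Shb, which encodes a signalling adaptor. The other 15 of the 20 longest lay in Rreb1, Hipk2, Mical3, Bcl2l1, Actn4, Zmiz1, Galnt10, Zfpm1, Ago2, Agfg1, Sept9, Slc22a23, Cmip and, as 2 separate domains, Ssbp3, with lengths from 55.4 kb down to 44.3 kb. The midpoint lay in an intron in each case except the Agfg1 domain, whose midpoint was intergenic. The Gse1 and Zfpm1 domains also lie within Gm20388, a long gene model that spans both. In all, 1549 of 62843 domains were at least 10 kb long (1234 in replicate 1's own list and 1590 in replicate 2's), against 160 without joining and 4077 with joining up to 3 kb. The longest was 48.2 kb without joining and 181 kb with joining up to 3 kb. Which domains were longest also depended on the joining distance, with 9 of the 20 overlapping the 20 longest without joining and 10 of them with joining up to 3 kb.

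In the replicated list, the peak with the highest fold by the authors' value, 16.2, was a single 48.2 kb peak in Zfpm1 on chromosome 8 from 122284292 to 122332504. In the replicates' own lists the longest part of this peak had folds of 11.4 and 17.4, below the highest folds of these lists, 16.1 and 18.3. The next in the replicated list was an intergenic peak of 8.89 kb on chromosome 1 from 181253987 to 181262872, with a fold of 15.7, whose nearest TSS was that of Wdr26 at 41986 bp. Peaks in introns of Zmiz1 (fold 15.6), Ssbp3 (15.5) and Vasp (15.3) followed. Then came a peak over the TSS of Kcnk7 with its midpoint in an intron (14.9). The last were peaks in introns of Rnf43 near the TSS of Supt4a (14.5), and of Zbtb7a (14.5), Sbno2 (14.4) and Tmem94 (14.4). Zbtb7a encodes a repressor of fetal globin genes. The least covered of the 10 was the Sbno2 peak in replicate 1, at 85.9% of its length, and the Zbtb7a peak in replicate 2, at 93.7%.

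Among loci of at least 50 kb, the highest percent covered in the replicated list was that of Tk1, the thymidine kinase of dividing cells, at 80.1% (67.7% in replicate 1 and 69.2% in replicate 2). Zfpm1 followed at 78.1% and was above Tk1 in both replicates' own lists (74.0% and 76.0%). Next in the replicated list were Vamp5 at 75.6%, Midn at 73.4%, Cbarp at 72.5%, Gm20708 at 72.0%, the water channel gene Aqp1 at 70.0%, Ppp1r9b at 69.8%, Rbm38 at 68.9% and Gpr146 at 68.2%. Each had a peak within 2 kb of its TSS. The Tk1 and Gm20708 loci overlap, as do those of Midn and Cbarp, so these values are not independent. The median over all protein-coding loci was 7.06%, with quartiles of 0.300% and 18.5%.

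Chromosome X had few peaks. The replicated peaks covered 7.17 kb per Mb of X and 49.1 kb per Mb of the autosomes, a ratio of 0.146 (0.126 in replicate 1 and 0.146 in replicate 2). Chromosome 12, whose gene density of 5.50 protein-coding genes per Mb is close to the 5.80 of X, had 39.5 kb per Mb. The autosomes ranged from 33.02 kb per Mb on chromosome 14 to 86.8 kb per Mb on chromosome 11.

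**Figure D5:**
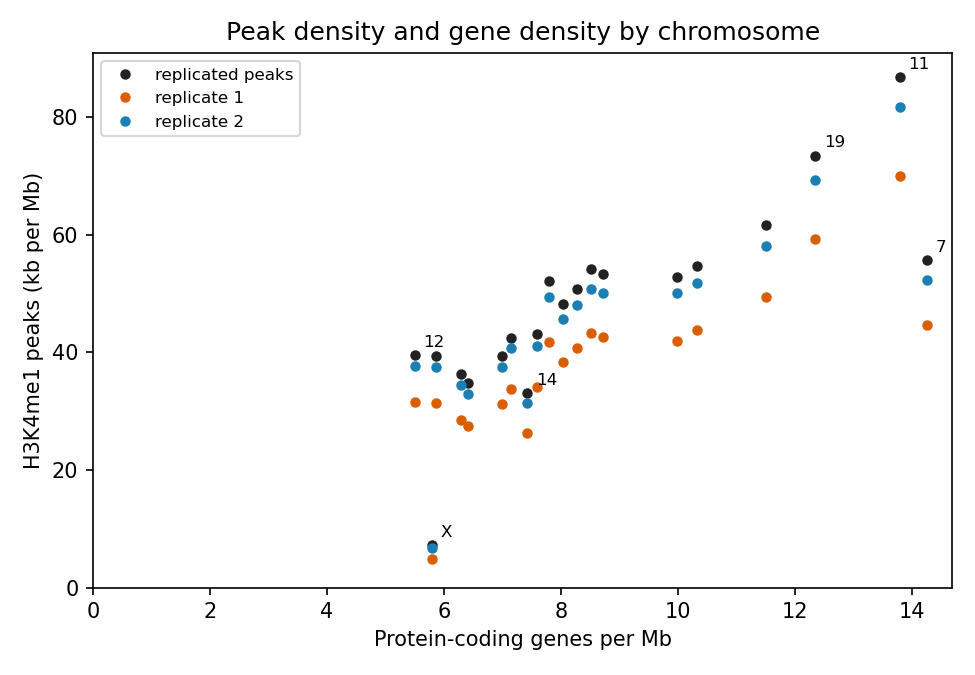
Kilobases of H3K4me1 peaks per Mb (y axis) against protein-coding genes per Mb (x axis) for chromosomes 1 to 19 and X, with dots for the replicated list and for each replicate. Chromosome X lies at 7.17 kb per Mb and chromosome 12, of similar gene density, at 39.5 kb per Mb.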

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

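Replicate 2 had 5 peaks and the pooled list 4 on scaffolds outside the main chromosomes, which the comparisons with genes and chromosomes left out, where a count of 0 would allow 3. In replicate 2, 3 of these were on Un_JH584304, with folds of 1.86, 1.70 and 1.43, as were 3 in the pooled list, with folds of 1.62, 1.48 and 1.40, and replicate 1 had 2 peaks on the same scaffold, with folds of 1.41 and 1.388.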

How the results depend on the processing

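The alternatives that matched lists on GC content, counted overlapping loci once, left out peaks near a TSS or took windows around the TSS were chosen after the data were seen. No called result changed direction. List percentiles were judged by their side of the threshold, counts of domains by a fixed ratio to the main count, and most other values by the spread between the replicates. Peak overlap was judged by the SD between replicate 1's share and replicate 2's share, which are different measures. Thus 66.7% of replicate 1's peaks, with 50% of the peak covered, counted as the same as 76.0%. By these rules 239 values under the alternatives stayed the same, 35 moved, 11 became past the threshold and 5 were no longer past it. A list that kept its side could still move far, as muscle did, from 35.08 to 92.24 with 100 kb of flank. Over 12 alternatives the erythroid and the stem and progenitor lists stayed at the 100th percentile, housekeeping lay between 99.86 and 100, and mature hepatocyte metabolism between 0.03 and 0.38. With 5 kb of flank the embryonic globins were at the percentile 97.45, coagulation and complement at 2.25 and megakaryocyte at 99.83. With 100 kb of flank the embryonic globins were at 89.5, heme synthesis at 90.98 and macrophage at 17.72. The megakaryocyte list became high at 97.58 to 97.94 in the replicates' own lists, 97.63 with the pooled peaks and 97.92 with unmatched lists. It was also high at 98.26 with a −log10 q of at least 5 and 98.24 with overlapping loci counted once. It stayed below the threshold at 94.59 with 100 kb of flank, 92.99 by number of peaks per 100 kb and 94.13 with matching on GC content. The same held at 92.14 with peaks near a TSS left out and 95.685 with windows around the TSS. With matching on GC content, stellate was at 0.47, muscle at 0.14, Hox at 0 and the olfactory receptors at 50, a tie of medians of 0 that places nothing. That value for Hox takes its 39 genes as separate, though they made 8 loci. A reciprocal overlap of 50% gave 41.3% of replicate 1's and 37.5% of replicate 2's peaks shared and a rho of 0.66, by construction fewer pairs, and 50% of the peak covered gave 50.4% for replicate 2. Promoter, exon, intron and intergenic shares were 18.5%, 5.62%, 51.0% and 24.9% with promoters within 2 kb. Counted in bp, exons held 7.12%, introns 57.3% and intergenic sequence 25.4%. With the pooled peaks, promoters held 7.76%, introns 56.5% and intergenic sequence 28.8%, and at a −log10 q of at least 5 promoters held 11.5% and introns 55.4%. In the replicates' own lists, promoters held 8.89% to 9.46%, exons 6.92% to 7.14%, introns 56.4% to 56.7% and intergenic sequence 26.7% to 27.8%. The TSS was covered in 14.8% to 17.0% in the replicates' own lists and 18.2% at a −log10 q of at least 5, and the downstream maximum was 2.16 to 2.18 and 2.07 times that value. The replicates' own lists are separate calls, and no replicated list was remade with a replicate left out. Of the 20 longest domains, 9 overlapped the 20 longest without joining, 10 with joining up to 3 kb, and 12 to 13 in the replicates' own lists. Domains of at least 10 kb numbered 160 without joining and 4077 with joining up to 3 kb. The ratio of X to autosomes was 0.126 to 0.146 in the replicates' own lists. The cause of these changes was not tested, except that joining less or more makes domains shorter or longer by construction. Unknown read depth limits which weak peaks were called.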

Other observations

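The gene groups and non-coding genes in this paragraph and the next were chosen after the data were seen, and some members, such as Tk1, Foxo3 and Rpl13a, had been seen to be high. The 79 ribosomal protein genes had a median of 22.9% of the locus covered (17.97% in replicate 1 and 21.6% in replicate 2) against 4.22% in matched random lists, at the 100th percentile with and without matching on GC content. Rpl6 was the highest at 65.8%, and 50 of the 79 lay above the 75th percentile of their matched genes. The 16 autophagy genes, whose products clear organelles from maturing red cells and serve all cells, had a median of 24.9% (20.0% and 24.0%), at the 99.99th percentile with and without matching on GC content, with the forkhead factor gene Foxo3 at 62.4%, the autophagy receptor gene Sqstm1 at 45.7% and the mitophagy receptor gene Bnip3l at 26.5%. The 22 DNA replication genes had a median of 15.5% (13.2% and 16.8%), at the 97.97th percentile, with the licensing factor genes Cdc6 at 59.2% and Cdt1 at 46.7%. That list was at the 88.46th percentile when lists were also matched on GC content. The 39 proteasome genes lay within the range at the 93.13th percentile. The 327 vomeronasal receptor genes were at 0, with no replicated peak at 315 of them, and lists matched on GC content also had a median of 0%, so that comparison could not place them.

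Loci of microRNA and long non-coding RNA genes, each with 20 kb on either side, differed widely. The locus of the erythroid microRNA genes Mir144 and Mir451a on chromosome 11 was covered over 54.0% (46.6% in replicate 1 and 48.1% in replicate 2) and 53.6%. That of Mir486 was covered over 26.8% (23.7% and 28.5%). Mir486 lies within Ank1, a member of the erythroid list, so its value is not independent of that list. The locus of Mir126a, a microRNA gene in an intron of Egfl7, was covered over 58.1% (45.1% and 54.5%) and that of the blood cell microRNA gene Mir142 over 44.5% (37.3% and 42.4%). The locus of Mir122, the main microRNA of hepatocytes, was covered over 2.68% (3.94% and 3.74%). Those of the muscle gene Mir1a-1 and the myeloid gene Mir223, which lies on X, had no peak, and Mir155hg and Mir124a-1hg were covered over 1.06% and 2.66%. The imprinted gene H19 was covered over 44.5% (34.6% and 37.3%), and Meg3, which is also imprinted, over 8.07% (8.60% and 6.17%). Neat1 and Malat1, neighbours on chromosome 19, were covered over 50.8% and 45.9%, and Mir17hg over 7.36%.

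The tests of GC content and of like-named neighbours for the liver and blood lists were chosen after their values had been seen. Gene density, GC content, repeats or like-named neighbours, each taken up separately, did not account for all of the low coverage of chromosome X. Matching on GC content, and to a smaller extent on repeats, brought the median of the autosomal lists closer to that of X. Either may thus account for part of the gap. GC content, repeats and like-named neighbours were not taken up together. The median of the 948 X loci was 0% (0% in each replicate), at the 0th percentile of autosomal lists matched on locus length and gene density (median 4.92%), on these and GC content (1.76%), and on these and soft-masked repeats (3.25%), and the 650 X genes without a like-named neighbour within 500 kb, with a median of 0.497%, were at the 0th percentile of such autosomal genes (7.41%). A peak within 2 kb of the TSS was present at 29.1% of X genes and 64.6% of autosomal genes, and the peaks of X genes had a median fold of 3.27 against 3.56. The highest X loci were Gm2174 at 31.8% and the interleukin receptor gene Il2rg at 24.8%, and Alas2 and Gata1 were at 23.0% and 20.4%. The copy number of X, which is lower in a pool of both sexes, the control reads and dosage compensation were not tested, and no biological explanation was tested.

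The low coverage of mature hepatocyte genes was still low against lists matched on GC content, at a percentile of 0.235. With matching on soft-masked repeats the percentile was 1.955, but 3.91% of the random lists also had a median of 0%, so the place below the threshold rests on how ties are split and repeats stay open. Reads shared between copies in tandem families remain a possible explanation for part of it, which the following comparison cannot decide. The 13 members without a like-named neighbour had a median of 1.87%, at a percentile of 8.80. The 13 with such a neighbour had a median of 0%, at 0.880. Both groups were placed among lists drawn from all genes, and so not among genes of their own kind. Autosomal genes without such a neighbour had a median of 10.8%, against 7.77% for all autosomal genes. The grouping goes by symbol alone, so a like-named neighbour, as counted for Slc10a1, need not be a near copy. With 13 members, the random lists without their lowest and highest 2.5% lay between 0.615% and 16.2%, so the members without a neighbour lie at the low side of the range without passing the threshold. No biological explanation was tested, since there was no second age or tissue.

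The high coverage of erythroid genes stayed at the 100th percentile with matching on GC content and with matching on soft-masked repeats. A candidate explanation is the mixture of cells, in which erythroid cells may outnumber hepatoblasts, so that peaks at erythroid genes stand higher, and the tables leave it open. The median over genes of the authors' peak fold was 3.67 at 35 erythroid loci and 3.11 at 29 hepatoblast loci, a difference of 0.563, beyond the −0.373 to 0.382 that held 95% of 10000 random relabellings of the genes. What stood apart depended on the measure. For the median fold per gene, a comparison with genes that had a peak, matched on locus length and gene density and chosen after the difference was seen, put the erythroid list at the 69.28th percentile (random median 3.59) and the hepatoblast list at the 0.14th (3.54). The median was 3.55 over all protein-coding genes with a peak and 4.02 for housekeeping genes, with 3.46 for the 11 mature hepatocyte loci with a peak and 3.21 for stem and progenitor loci. For the highest fold per gene, which can rise with the number of peaks at a locus, the median was 8.83 for erythroid, 4.96 for hepatoblast and 6.32 for all protein-coding genes with a peak, and it was not compared with matched genes. The share of each cell type was not measured, and no biological explanation was tested.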
